A study of Homo sapiens with 10 samples.

How the data were processed

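The series holds 10 libraries of MEL624 melanoma cells: 4 ATAC-seq libraries, 4 H3K27ac ChIP-seq libraries and 2 inputs. Groups and replicate numbers come from the sample titles, which read WT or KD for ATAC-seq and shNC or shFTO for ChIP-seq, while the genotype label is WT or FTO KD in both assays. WT and shNC are both called control here. Whether the ATAC-seq control cells carried a control hairpin is not given in the sources used here. The 6 peak lists analysed are 4 for H3K27ac, 1 per library, and 2 for ATAC-seq, 1 per condition. How the 2 ATAC-seq libraries of a condition were combined is not given in the sources used here, and no separate file of the inputs was used.

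The submitters' processing notes name Trim Galore, Bowtie2, deepTools and MACS2, with no versions, and the builds hg19 and mm9. Positions are given here in hg19, the human one. The deposited lists have 10 columns in the narrowPeak layout with no header. The authors' values per peak are a fold enrichment (a linear ratio over background) and a p-value and q-value as −log10, and these are the authors' own. The lowest −log10 q lay between 1.31 and 1.54 over the 6 lists, near the value of a q of 0.05. Fold was used to describe, rank or filter peaks within a list, together with p to recover the background as described further on, and for classes that stratify 1 odds ratio. The ATAC-seq lists hold several rows for some intervals (837934 rows and 470823 intervals in the control, 525115 and 381406 in the knockdown). The row of highest fold was kept. Chromosome Y and unplaced sequences were left out.

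Peaks of the lists of an assay were merged into regions where they overlapped by at least 1 bp, and a region counted as present in a list with any peak there. H3K27ac regions with a peak in both libraries of one condition and none in the other were counted, and so were those of the other 2 ways to split the 4 libraries. Jaccard indices were computed on covered bases. Peak number, covered length and median width were compared by exact permutation, with a smallest two-sided p of 0.333. ATAC-seq lists were compared by overlap with no test between conditions. The direction in both assays was tested with Fisher's exact test over H3K27ac regions that met ATAC-seq regions of 1 list alone. Chance overlap was taken from 100 circular shifts. Chromosomes were compared with Fisher's exact test and Benjamini-Hochberg adjustment over 23 chromosomes, a test chosen after the data were seen. The circular shifts were not part of the plan either. The other tests just named were fixed before the data were examined.

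MACS2 is taken to give fold = (k + 1) / (λ + 1) and p as the Poisson chance of more than k reads at background λ. The pair of a whole pileup k and a λ that meets both was found per peak, and it reproduced −log10 p within 0.001 for at least 99.9995% of the peaks of each list. In the ATAC-seq lists at least 99.9995% of peaks had the same λ, so a single genome-wide background was used there. In the H3K27ac lists 21.0 to 24.0% of peaks lay at the genome-wide λ and the rest above it, at a local background. That the local background comes from the inputs is inferred from its correlation within conditions and is not stated in the labels. Windows of 5 Mb with at least 30 common regions were used. A window was low under a centred log2 ratio of -0.12, about 3 times the SD between libraries of a condition (a spread that leaves out variation between inputs). A segment was made of 3 or more neighbouring low windows. A window with fewer than 30 common regions did not end a segment, so segments can span stretches where the background was not measured. Read totals are not in the lists, so read depth per library is unknown beyond these backgrounds, which were 1.40, 1.18, 1.23 and 1.19 for control libraries 1 and 2 and knockdown libraries 1 and 2. These values scale with fragment length. Divided by the width of the shortest peak of each list, taken as the fragment length, they were 0.00754, 0.00709, 0.00647 and 0.00609 per bp in the same order, a ratio of means of 1.16 for control over knockdown. They give the depth of a library only where the caller did not scale it to its input.

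The named regions are, for each assay and direction, the 5 of highest fold percentile within their own list, taking the lower percentile of the 2 libraries for H3K27ac, with ties ordered by chromosome and start. This is the rule fixed for the case that no annotation of the files' build is at hand. The gene table here is of GRCh38.p14, so promoter and gene-body shares, 15 gene lists and the cell type markers were not analysed here, and neither were LINE1 elements. Other settings tried, also fixed beforehand, were a stricter threshold (−log10 q of at least 5), equal numbers of peaks, another overlap rule, merging of peaks under 500 bp apart, 2 thresholds for presence and absence, each H3K27ac library left out, and pairing by replicate number.

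The overlap and background code was tested on simulated data. From 153435 regions with 200 lost and 200 gained set by hand, 200 and 200 were found, and for 4930 simulated peaks the pileup and background were recovered for 100% within 0.001. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.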

Results

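FTO removes the N6-methyl mark from adenosines in RNA, and it was knocked down with a short hairpin in MEL624, a human melanoma cell line. The labels give 4 ATAC-seq libraries, 2 of control and 2 of knockdown cells, which map accessible DNA. They also give 4 ChIP-seq libraries for acetylated lysine 27 of histone H3 (H3K27ac), a mark of active promoters and enhancers, again 2 per condition, and 1 input library per condition. Control cells are titled WT in ATAC-seq and shNC in ChIP-seq, so the 2 assays may not share the same control. The question the design puts is whether accessible and acetylated regions differ once FTO is reduced. Peak lists hold no RNA level, so the extent of the knockdown was not measured here. H3K27ac has a list per library, with 111987 and 135059 peaks in control libraries 1 and 2, and 116270 and 101375 in knockdown libraries 1 and 2, on chromosomes 1 to 22 and X. ATAC-seq has 1 list per condition, with 470593 intervals for the control and 381136 for the knockdown.

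The acetylated part of the genome was of similar size in both conditions. H3K27ac peaks covered 75.3 ± 4.21 Mb in control and 73.3 ± 3.40 Mb in knockdown libraries (SD, n = 2 each; exact permutation test, two-sided, p = 0.667). The number of peaks was 123523 ± 16314 in control and 108822 ± 10532 in knockdown libraries (SD, n = 2 each; exact permutation p = 0.667). Median peak width was 374 ± 63.6 bp and 420 ± 25.5 bp in the same order (SD, n = 2 each; exact permutation p = 0.667). With 2 libraries per condition such a test cannot go below 0.333, and nothing in the labels says whether the libraries of a condition came from separate cultures, so these p-values measure only the spread between these libraries. The 2 control libraries shared less of their covered bases with each other (Jaccard index 0.564) than control library 1 shared with knockdown library 2 (0.620). The mean index was 0.590 within and 0.584 between conditions, a difference of 0.00597 (exact permutation over the 3 ways to split the libraries, two-sided, p = 1). It became -0.0139 without knockdown library 1 and -0.0255 without knockdown library 2, and the difference in covered length, knockdown minus control, turned to 0.907 Mb without control library 1 and 0.335 Mb without knockdown library 2.

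Regions that differed in the presence of an H3K27ac peak were mostly weak. Merging the 4 lists gave 153435 regions, of which 51506 (33.6%) held a peak in every library. Peaks were present in both control libraries and in neither knockdown library at 6004 regions (3.91%), called lost here, and in both knockdown libraries and neither control library at 3612 regions (2.35%), called gained. These shares are of all regions, also those with a peak in 1 library only, which cannot be lost or gained. Control library 2 alone held 25992 of those. Among 24010 regions with a fold of at least 8 in both control libraries, 10 (0.0416%) were lost, and among 23406 with that fold in both knockdown libraries, 5 (0.0214%) were gained. A strong region must fall below the calling threshold to count as lost, so these low shares follow in large part from counting presence and do not exclude partial changes of strong regions. The median region was 370 bp wide for lost, 389 bp for gained and 1200 bp for common regions. Common regions merge peaks of more libraries, so part of this gap follows from the merging.

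The count of differing regions stood little above the higher count of the unrelated groupings (1.12 times, and 1.02 to 1.29 times in the other settings). Control against knockdown gave 9616 lost and gained regions together. Grouping control library 1 with knockdown library 2, against control library 2 with knockdown library 1, gave 8615 regions, and grouping by replicate number gave 4610. Lost regions outnumbered gained ones 1.66 to 1, but with the same number of peaks taken from each list the counts became 3897 lost and 4471 gained. The genome-wide background per bp was higher in both control lists than in both knockdown lists (ratio of means 1.16), the direction in which lost regions outnumber gained ones. Across libraries it did not follow the number of peaks. Control library 1 had the highest value (0.00754) but 111987 peaks, fewer than control library 2 (135059) and knockdown library 1 (116270). These backgrounds give depth only where the caller did not scale a library to its input. Leaving out a library sets 1 library against 2 and favours the side with 1, so the ratios of 4.25 and 3.00 without control library 1 or 2, and 0.935 and 0.424 without knockdown library 1 or 2, do not test its stability.

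**Figure D1:**
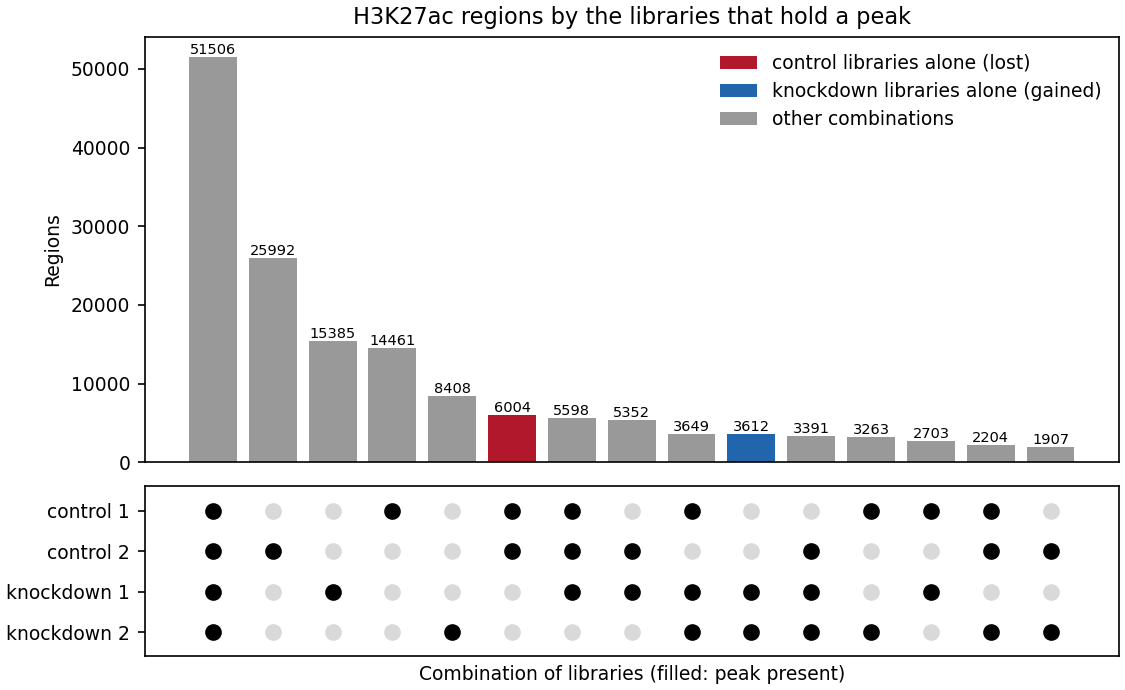
Bars give the number of H3K27ac regions (vertical axis) for each combination of libraries that hold a peak there, with filled circles marking the libraries. Regions in all 4 libraries number 51506, and the regions of the control libraries alone (6004) and of the knockdown libraries alone (3612) are of the same order as combinations that mix the conditions, such as 5352 for control library 2 with knockdown library 1.

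The lost region of highest rank lay on chromosome 3 from 197692941 to 197695397 (hg19), 2457 bp wide, with the authors' fold of 10.9 and 12.5 in the control libraries and no ATAC-seq peak in either list. The next was on chromosome 7 from 155561900 to 155562478. The other 3 lay within 1 Mb of each other near the end of the long arm of chromosome 18, from 77235942 to 77237243, from 76265426 to 76266347 and from 77237348 to 77238196. The gained region of highest rank was on chromosome 4 from 116864307 to 116865294, with folds of 9.22 and 9.14 in the knockdown libraries. It was followed by regions on chromosome 11 from 73845512 to 73846147, chromosome 7 from 153214844 to 153215771, chromosome 3 from 8530707 to 8531191 and chromosome 13 from 106650171 to 106650629. None of these 10 regions lay in the low-background segments described further on. The last lay within the span of the high-background segment, in a 5 Mb window with too few common regions for its background to be measured. Genes at these positions were not looked up, since the gene table at hand is of another genome build.

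Lost and gained regions were spread unevenly over chromosomes. Chromosome 5 held 440 lost and 130 gained regions, an odds ratio of 2.12 against all other chromosomes (Fisher's exact test, two-sided, adjusted p = 1.24e-13 over 23 chromosomes). By the same exact test chromosome 20 held 267 and 58 (odds ratio 2.85, adjusted p = 1.24e-13), and chromosome 21 held 105 and 21 (odds ratio 3.04, adjusted p = 2.47e-06). Chromosomes 17 and 22 also had more lost regions (odds ratios 1.38 and 1.64), while chromosomes 4, 6, 12, 13 and X had fewer, with 129 lost and 143 gained on X. In the grouping of control library 2 with knockdown library 1, the odds ratio was 0.664 for chromosome 5 and 1.18 for chromosome 21, but 2.56 for chromosome 20, 2.51 for chromosome 17 and 6.01 for chromosome 22. The grouping by condition thus gave the higher odds ratio for chromosomes 5, 20 and 21 and the lower one for chromosomes 17 and 22, and these differences were not tested. Regions are not independent replicates, so the tests compare these lists.

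The accessible genome was listed as larger in control than in knockdown cells. Of 510684 ATAC-seq regions, 234476 (45.9%) were in both lists, 218913 (42.9%) in the control list alone and 57295 (11.2%) in the knockdown list alone, a ratio of 3.82. The lists covered 257 Mb and 161 Mb, and 85.8% of the bases of the knockdown list lay in the control list. Regions of the control list alone were narrow and weak, with a median width of 217 bp against 549 bp for shared regions, and a median fold of 2.90 against 4.24 in the control list. Shared regions merge peaks of both lists, so part of the gap in width follows from the merging. Each condition has 1 list, so there is no replicate check and no p-value between conditions.

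Regions of the knockdown list alone also had a lower median fold (3.60) than shared regions in that list (4.25), and here too presence does not show partial changes of strong regions. Regions of the control and the knockdown list alone numbered 20589 and 12842 from a fold of 4 up, but 1601 and 3705 from a fold of 5 up. The genome-wide background that the peak caller used, recovered from the authors' fold and p-value of each peak, was 3.48 for the control and 2.06 for the knockdown list, a ratio of 1.69. The control list thus rests on more reads per base if both were made alike, and the same fold stands for unlike pileups in the 2 lists, so these counts give no direction. With the same number of peaks in both lists, the ratio of control-alone to knockdown-alone regions was 2.01. Equal numbers of peaks do not equalise depth or peak width (median 298 bp in the whole control list, 270 bp in the whole knockdown list). A wide peak can meet several of the other list, so this ratio gives no direction either.

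The strongest region of the control list alone was on chromosome 8 from 134538843 to 134539714 (fold 9.15). It was followed by chromosome 15 from 78269132 to 78269353, and by 3 regions of chromosome 20, from 62439013 to 62439332, from 62674767 to 62675037 and from 55693106 to 55693621. The strongest region of the knockdown list alone was on chromosome 8 from 40065800 to 40066372 (fold 11.4), followed by chromosome 2 from 55970760 to 55971052, chromosome 7 from 18509064 to 18509347, chromosome 8 from 93140477 to 93140794 and chromosome 1 from 118965888 to 118966355. The 3 regions of chromosome 20 and that on chromosome 7 lie in the low-background segments described further on, and the other 6 do not. None of the 10 overlapped an H3K27ac region common to the 4 libraries, and 1 of them, that on chromosome 8 from 134538843, overlapped any H3K27ac region.

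Regions acetylated in all 4 libraries were mostly accessible in both conditions. Of the common H3K27ac regions, 89.9% overlapped a control ATAC-seq region and 89.0% a knockdown one, against 22.8% and 18.5% after shifting them along their chromosomes (mean of 100 circular shifts). Lost regions overlapped control ATAC-seq regions in 60.7% and knockdown ones in 50.7% of cases, and gained regions in 48.9% and 49.1%. Some lost or gained regions met ATAC-seq regions held by 1 list alone. Those of the control list alone were met by 865 lost regions and those of the knockdown list alone by 148, against 278 and 269 gained regions. Such a region may also meet ATAC-seq regions shared by both lists. Without any knockdown ATAC-seq region, 729 lost regions met the control list. The odds ratio was 5.66 (95% interval 4.44 to 7.20; Fisher's exact test, two-sided, p = 1.65e-47). Regions are not independent replicates, so the interval and p-value compare these lists and not the conditions. The same comparison in the unrelated grouping of control library 1 with knockdown library 2 gave an odds ratio of 0.202 (0.152 to 0.268), which is nearly as far from 1, and grouping by replicate number gave 0.521 (0.369 to 0.737), which is nearer to 1. Without control library 2 the odds ratio was 2.79, without knockdown library 1 it was 3.46 and without knockdown library 2 it was 2.08.

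Whole segments of chromosomes differed in the background beneath the H3K27ac peaks. The local background recovered for each peak, taken relative to the genome-wide value of its own list, was averaged over common regions in 502 windows of 5 Mb and centred on the median window. In 6 segments it was lower in the knockdown lists: chromosome 5 from 50 to 85 Mb (log2 ratio -0.34) and from 105 to 185 Mb (-0.28), chromosome 7 from 0 to 80 Mb (-0.21), chromosome 11 from 115 to 135 Mb (-0.26), chromosome 20 from 0 to 65 Mb (-0.27) and chromosome 21 from 15 to 50 Mb (-0.23). On chromosome 13 from 50 to 115 Mb it was higher (0.22 over the 6 windows measured in that span). Over all windows the robust SD of the ratio was 0.06. Between the 2 libraries of a condition the ordinary SD of their ratio was 0.04 in both conditions, which leaves out variation between inputs. Background values of the same condition correlated at Spearman's rho 0.765 and 0.770 across 51506 common regions, against 0.481 to 0.486 between conditions, so the libraries of a condition are not independent in this measure.

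The ATAC-seq lists, made from other libraries, differed in the same segments. Of control ATAC-seq regions with a fold from 4 to 5, 4801 of 12410 (38.7%) inside the 6 low segments were missing from the knockdown list, against 14187 of 65583 (21.6%) outside them (odds ratio 2.29, 95% interval 2.19 to 2.38). In the high segment of chromosome 13 the share was 14.6% (122 of 836). This fold class was not part of the planned comparisons. Over control regions of all folds, 41869 of 70798 (59.1%) were missing inside the low segments and 177044 of 382591 (46.3%) outside them. H3K27ac had 1055 lost and 244 gained regions inside the low segments and 4949 and 3368 outside (odds ratio 2.94, 2.54 to 3.40; Fisher's exact test, two-sided, p = 1.66e-55). It had 54 lost and 87 gained regions in the high segment. The other groupings of the libraries gave odds ratios of 0.781 and 0.790 in the low segments. The rule for a segment was set after the data were seen. As regions are not independent replicates, these intervals and the p-value compare the lists and not the conditions.

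**Figure D2:**
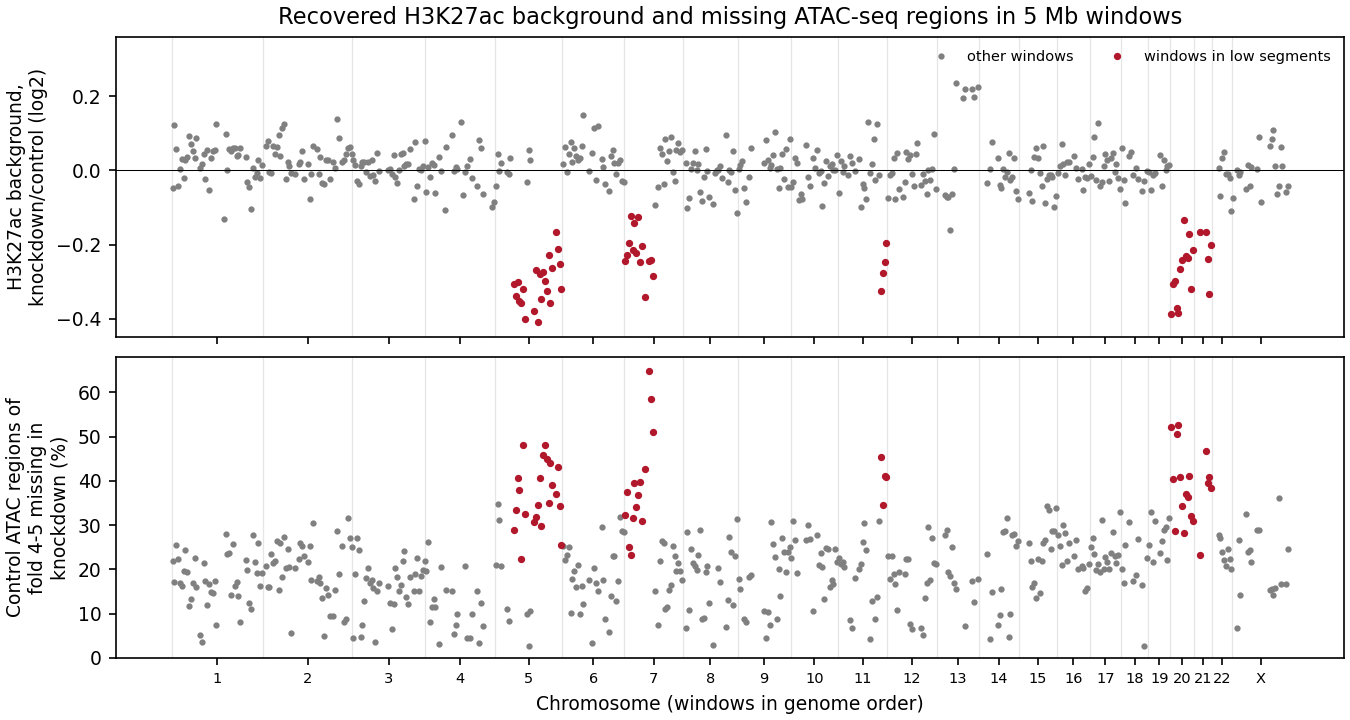
Points are 5 Mb windows in genome order (horizontal axis, by chromosome), with windows of the low segments in red. The upper panel gives the H3K27ac background of the knockdown over the control lists (log2, centred), which falls to -0.41 on chromosome 5, and the lower panel the share of control ATAC-seq regions of fold 4 to 5 that are missing from the knockdown list (%), which is 38.7% over the red segments and 21.6% elsewhere.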

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

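The segments and the tests of their background, of GC, of read depth and of fold percentile were chosen after the results were seen, while the tests by odds ratios stratified by window and by fold class and by the other groupings between the assays were set before their values were computed. The background under H3K27ac peaks, a quantity outside the planned comparisons, stood apart from the rest of the genome in 7 segments. Its centred log2 ratio of knockdown over control was -0.34 on chromosome 5 from 50 to 85 Mb, -0.28 on chromosome 5 from 105 to 185 Mb, -0.21 on chromosome 7 from 0 to 80 Mb, -0.26 on chromosome 11 from 115 to 135 Mb, -0.27 on chromosome 20, -0.23 on chromosome 21 and 0.22 on chromosome 13 from 50 to 115 Mb.

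The loss of peaks on chromosomes 5, 20 and 21 goes with these segments, although for H3K27ac chromosome 20 stood out nearly as much in the grouping of control library 2 with knockdown library 1 (odds ratio 2.56, against 2.85 by condition). A GC-dependent difference in the background, and so between inputs if it comes from them, is argued against. The mean centred background of chromosomes 17, 19 and 22, which are rich in GC, was 0.0017, while that of chromosomes 5, 20 and 21 was -0.23. GC differences between the H3K27ac or the ATAC-seq libraries themselves are not addressed by these values. The ATAC-seq ratio of control-alone to knockdown-alone regions was 3.82 in all. It was 5.58, 8.79 and 6.38 on chromosomes 17, 19 and 22, and 7.12, 15.3 and 11.3 on chromosomes 5, 20 and 21. Of control ATAC-seq regions with a fold from 4 to 5, 24.3% were missing from the knockdown list in all. The share was 23.4, 27.1 and 23.6% on chromosomes 17, 19 and 22, and 35.6, 37.6 and 39.2% on chromosomes 5, 20 and 21. Fewer DNA copies of these segments in the knockdown cells are a candidate explanation, as the mean background of each of these 3 chromosomes (-0.21 or lower) lay below that of each of the 20 others (-0.09 or higher, SD 0.03), and ATAC-seq, from other libraries, lost regions in the same places. How far 2 inputs of the same condition would differ is not known. A change of chromatin through FTO cannot be told apart from fewer DNA copies here, although all 13 windows of chromosome 20 were low. Background is known only at peaks and, if it comes from the inputs, from 1 input per condition.

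The ATAC-seq control list held 3.82 times as many regions alone as the knockdown list. DNA copies of the low segments as the whole cause are argued against by a ratio of 3.30 outside them. Lower read depth of the knockdown list may account for part of it: with pileups divided by the ratio of the backgrounds, 32.4% of control-alone regions would lie under the smallest pileup of the knockdown list, 7, and their median would be 7.1. Counting noise adds to this by an amount that was not modelled, so depth and an effect of the condition cannot be told apart with 1 list each. A loss of weakly accessible sites through FTO knockdown stays open.

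Lost H3K27ac regions met control-alone ATAC-seq regions more often than gained ones, with an odds ratio of 5.66. DNA copies that differ over whole 5 Mb windows, as the whole cause, are argued against by an odds ratio of 3.36 (95% interval 2.41 to 4.68) when stratified by 5 Mb window. That estimate used 775 regions in 153 windows, against 1560 regions in the fold strata. Copy changes smaller than a window are not removed by these strata and stay open. Inside the low segments the odds ratio was 2.16 (0.745 to 6.28), an interval that includes 1, and outside them 5.20 (4.02 to 6.71). It was 5.69 when stratified by class of H3K27ac fold and 5.52 by fold percentile within its own list. The median of the lower fold of the 2 libraries hardly differed between lost and gained regions (4.01 and 4.11), so these strata could change little. Strength of the ATAC-seq regions was not stratified. The grouping of control library 1 with knockdown library 2 gave 0.202, nearly as far from 1 as 5.66, and that by replicate number 0.521, nearer to 1. A property of the libraries that is unrelated to FTO may thus be enough to give a value like 5.66. The first of these groupings was also uneven over chromosomes, with odds ratios of 2.46, 2.51, 3.57, 2.56 and 6.01 on chromosomes 16, 17, 19, 20 and 22 for the regions of control library 2 with knockdown library 1. An effect of FTO on both assays stays open and was not separated from it.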

How the results depend on the processing

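Exclusion of the low segments, coverage of 50% of a region, the strata and the leaving out of libraries for the Jaccard index were chosen after seeing the data. Lost and gained H3K27ac counts were 3335 and 2555 at −log10 q of at least 5, 3897 and 4471 with equal numbers of peaks (ratio 0.872, reversed), 3274 and 1879 with peaks under 500 bp apart merged, and 1319 and 885 with 2 thresholds. Leaving out a library gave 8570 to 34148 lost and 7320 to 20202 gained regions and a ratio from 0.424 to 4.25, where the rise in counts and the shift of the ratio towards the side left with 1 library follow from setting 1 library against 2. The Jaccard difference ranged from -0.0255 to 0.0533, and was -0.0139 without knockdown library 1. The difference in covered length, knockdown minus control, ranged from -5.05 to 0.907 Mb, being 0.335 Mb without knockdown library 2. For the changes of sign in these 2 differences, and for the reversal with equal numbers of peaks, the cause was not tested.

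ATAC-seq counts in the control and the knockdown list alone were 90979 and 24280 at −log10 q of at least 5, 101847 and 35013 with merging, and 32418 and 8341 with 2 thresholds, where stricter thresholds and merging leave fewer regions by construction. With equal numbers of peaks their ratio was 2.01, and in every alternative run it stayed above 1. None of these alternatives equalises read depth between the lists. The odds ratio between the assays stayed above 1 in every alternative run, from 2.08 to 10.8. The overlap of at least 50% of the shorter of peak and region changes nothing by construction, since peaks lie wholly inside their regions, and has no meaning for an index in bases. The alternatives for promoters, locations and gene lists were not run, as no annotation of hg19 was used.

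Replicate numbers did not pair the H3K27ac libraries by their presence deviations (correlation -0.0572 over 153435 regions). In the replicate block the counts of 6004 and 3612 are those of the main comparison by construction. The paired differences in peak number, covered length and median width were -14700.5 (exact sign-flip p = 1), -2.07 Mb (p = 0.5) and 46 bp (p = 1), where the smallest p possible is 0.5. Read depth limits all lists, and weak regions near the threshold are the ones most open to it.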

Other observations

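Lost H3K27ac regions came in runs, a test chosen after the runs were seen. Among regions with peaks in at least 2 libraries, 11 lost regions in a row lay on chromosome 11 from 116183478 to 116434280, where ATAC-seq had 117 regions in the control list alone, 6 in the knockdown list alone and 25 in both. Another 10 in a row lay on chromosome 18 from 844711 to 950740, outside the low segments, with 11, 1 and 13 ATAC-seq regions in the same order, and 7 on chromosome 21 from 43537425 to 44144971. The runs on chromosomes 11 and 21 lie in low segments, where lost regions are frequent. With the states permuted within 5 Mb windows, which keeps the number of lost regions of each window, the longest run of lost regions in 100 permutations was 6. Gained regions reached a run of 4, and these permutations reached 6. Runs in the other groupings of the libraries were not counted here, so the runs cannot be tied to the condition.

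The widest regions with H3K27ac in all 4 libraries were on chromosome 15 from 58729722 to 58754340 (24619 bp), chromosome 1 from 9492333 to 9512352 (20020 bp), chromosome 5 from 56735388 to 56754396 (19009 bp), chromosome 2 from 206546332 to 206563760 (17429 bp) and chromosome 19 from 42960660 to 42977573 (16914 bp).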
